A study of Danio rerio and Mus musculus with 18 samples.

How the data were processed

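RNA was sequenced from adipose tissue of zebrafish and mice in 18 libraries, 3 in each of 6 groups. Per the labels' protocols, adipocytes were collected and total RNA was prepared with TRIzol. The zebrafish libraries were made with the SMARTer Stranded Total RNA-Seq Kit v3 and the mouse libraries with a stranded Illumina total RNA kit after depletion of ribosomal RNA. Epicardial adipose tissue (eAT) is the fat on the surface of the heart, and visceral adipose tissue (vAT) is the fat around the abdominal organs. The groups were taken from the sample titles: eAT and vAT of adult female zebrafish, eAT of zebrafish kept at 27 °C (control) or cooled to 18 °C and kept there for 24 h (cold), and eAT of young and of aged female mice. The ages of the mice are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be in part technical.

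The authors deposited 1 table for each comparison, each normalized on its own, so every test was made within a table. The eAT and vAT table holds a signal deposited by the authors, the read count per gene divided by 1 size factor per library. It was made with STAR 2.7.3a, DESeq2 1.32.0 and genome GRCz11, per the submitters' processing notes and the values. The cold table and the mouse table hold variance-stabilised values on a log2 scale, made by the authors with kallisto 0.46.1 and DESeq2 1.34.0 on GRCz11 and GRCm39, per the submitters' processing notes. The annotation releases and the filters on genes are not given in the sources used here. On the variance-stabilised scale a gene without reads sits at the table's lowest value, 7.33 in the cold table and 6.31 in the mouse table, and differences between low values are compressed, so the change of a weakly expressed gene is understated. Values of this kind are not divided by transcript length, so a long transcript such as that of titin reads high.

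In the eAT and vAT table each value was divided by the lowest value above 0 of its library. Of the 192342 quotients, 99.9995% lay within 0.01 of a whole number, and the rounded quotients were used as whole reads. The libraries then held between 23315508 and 41984753 reads. The depth of the other libraries is unknown. Replicates were compared before they were averaged. In the eAT and vAT table the chi-square statistic per degree of freedom between replicates lay between 25.1 and 190.4, far above sampling noise, and in the other tables replicates correlated with Pearson's r between 0.956 and 0.984 across genes without shared columns of values, so every library was counted as 1 replicate. Columns of the eAT and vAT table match single samples by name. Columns of the other tables show the group only, so the libraries are named here by column: cld1 to cld3 (cold), ctr1 to ctr3 (control), o1 to o3 (aged) and y1 to y3 (young).

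Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), on log2(normalized count + 1) in the eAT and vAT table and on the deposited values in the others. A fold on the log2(normalized count + 1) scale understates the change of low genes. Genes were kept with a mean of at least 10 normalized counts, or of at least 1 above the lowest value of a variance-stabilised table. Gene lists for cell types and pathways were tested with limma's camera at a preset correlation between genes of 0.01, over lists with at least 5 measured members, and again with an estimated correlation. The lists, the filters, these gene and list tests and their alternatives were fixed before the data were examined, and so was the rule for named genes. Per comparison it names the 5 largest rises and the 5 largest falls among genes past the threshold that have a symbol. Their libraries must not overlap between groups, and their higher group must average at least 100 normalized counts or at least 3 above the lowest value. It also names the 2 members with the largest change past the threshold in the list's direction (otherwise the 2 with the smallest p) for each of the 8 lists with the smallest p. It adds a few fixed names (Ucp1, Ppargc1a, Prdm16, Cidea, Dio2, Fabp4, Plin1, Lep, Adipoq and Cdkn2a in mouse). Most genes named outside that rule are said to be so where they appear. The others are Cpt1b, named as a shared list member, and genes shown in a figure only.

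Mouse gene IDs were matched to symbols for 18823 of 18912 IDs (99.5%). The zebrafish files do not pair their gene IDs with names, and none of the 49597 genes of the zebrafish RefSeq table used for reference carries such an ID. The zebrafish lists and the fixed zebrafish names were therefore not tested, and the rule's demand for a symbol could not be kept there. The 2 IDs with the largest rise and the 2 with the largest fall that met its other demands are given per zebrafish comparison instead. Gene lengths and GC content came from the longest GENCODE M21 transcript of each gene. That release is built on an older mouse assembly than the one the authors used, so no coordinates are given.

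The tests were run on simulated data with 200 changed genes per table. The simulated sizes were set after a first run in which DESeq2 made too many false calls, and only limma and edgeR were then required to keep them low. In the eAT and vAT design limma recovered 0% of the genes changed by 1 on the log2 scale, 33.8% of those changed by 2 and 87.9% of those changed by 4 (13934 genes). In the cold design it recovered 14.9%, 77.6% and 98.5% of genes changed by 0.5, 1 and 2 (10059 genes), and in the mouse design 16.4%, 85.1% and 100% (12345 genes). False calls made up 4.76%, 3.05% and 3.60% of limma's calls. On the simulated eAT and vAT reads 16.8% of DESeq2's calls were false.

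The alternatives were pseudocounts of 0.5 and 5, no filter and stricter filters (a mean of at least 50 normalized counts, or of at least 3 above the lowest value), TMM scaling, a shift to one median, quantile normalization, eBayes without the trend or in its robust form, the replicate number as a block, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the whole reads, an estimated correlation in camera, and each library left out in turn. No table held columns of other samples.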

Results

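The series profiled fat attached to the heart. In zebrafish, eAT was compared with vAT (3 libraries each) and eAT of fish at 27 °C with eAT of fish held at 18 °C for 24 h (3 each). In mice, eAT of young animals was compared with eAT of aged animals (3 each). The title of the series presents the zebrafish depot as a thermogenic, beige-like fat comparable to human epicardial fat, so the comparisons ask how eAT differs from another depot, how it responds to cold and how it changes with age. The whole reads recovered for the eAT libraries numbered 41984753, 32466637 and 32390575, and those for the vAT libraries 23315508, 25306524 and 27955959. Depth was unknown in the cold and mouse tables, where between 17826 and 22324 genes per library lay above the table's lowest value.

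The eAT and vAT libraries of zebrafish differed widely in the RNA they held. Of 14543 genes tested, 2226 passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), 1161 of them higher in eAT and 1065 lower, with a median absolute change of 3.07 on the log2 scale. At the extremes, 25 genes were more than 10 log2 units higher in eAT and 44 more than 10 log2 units lower. The 44 genes together took 9.28% ± 0.985 of the reads in vAT (SD, n = 3) and 0.000503% ± 0.000151 in eAT (SD, n = 3). The 25 genes took 3.06% ± 2.19 of the reads in eAT (SD, n = 3) and 0.000174% ± 0.000107 in vAT (SD, n = 3), and their share in eAT replicate 1, 5.59%, was well above those of replicates 2 and 3, 1.76% and 1.84%. The files do not pair the zebrafish IDs with gene names.

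Among genes that met the rule for named genes in all but a symbol, the largest rise was that of ENSDARG00000079782, with 76049 ± 14600 normalized counts in eAT (SD, n = 3) against 2.53 ± 2.57 in vAT (SD, n = 3), a log2 change of 14.73 (SE 0.567, limma adjusted p = 7.95e-08). ENSDARG00000042535 followed at 31157 ± 13500 normalized counts in eAT (SD, n = 3). Its vAT libraries held 2 reads in all, which puts the ratio of the means at 17700 with a counting interval from 4890 to 146000 (95%, exact Poisson). The largest falls were those of ENSDARG00000073742, with 568983 reads summed over the vAT libraries and 10 over the eAT libraries (log2 change −17.18, SE 0.402, limma adjusted p = 4.99e-09), and of ENSDARG00000042993, with 519292 reads in vAT and 17 in eAT (log2 change −16.73, SE 0.638, limma adjusted p = 7.40e-08). These 4 changes lie on the log2(normalized count + 1) scale, so their size depends on the pseudocount, and counting intervals leave out all variation but counting error. Among the calls, 96 genes had no read in vAT and 31 had none in eAT. With those genes set to the bound that 3 reads over a group allow, the median absolute change was again 3.07. The filter on mean counts keeps these bounds above that median, so it could hardly move and the repeat is no check.

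A few features held most of the reads. The 10 most abundant features of each library took 77.0% ± 5.51 of the reads in eAT (SD, n = 3) and 81.3% ± 0.579 in vAT (SD, n = 3). The 2 features that were most abundant in vAT took 58.7% ± 0.749 there (SD, n = 3) and 23.4% ± 1.14 in eAT (SD, n = 3), while the most abundant feature of eAT took 33.3% ± 4.84 in eAT (SD, n = 3) and 1.24% ± 0.348 in vAT (SD, n = 3). Outside the 10 most abundant features, the libraries kept between 4370113 and 12246725 reads. The vAT libraries were less alike (Pearson's r across genes between 0.725 and 0.786) than the eAT libraries (between 0.916 and 0.939). The count of calls was 1315 without eAT replicate 1, 1334 without eAT replicate 2 and 1353 without eAT replicate 3.

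**Figure D1:**
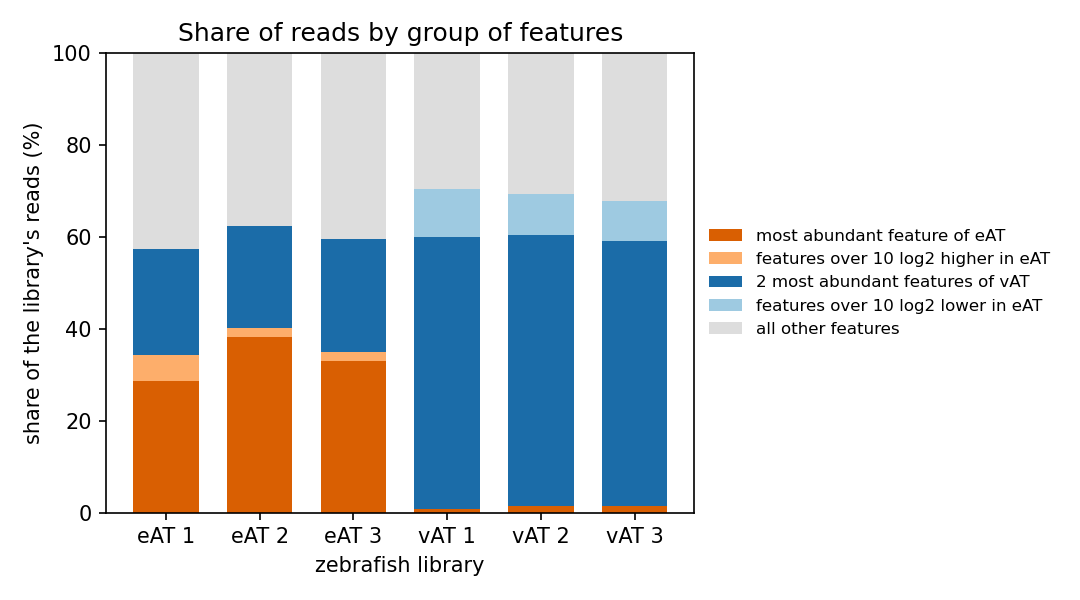
Share of each zebrafish library's reads (percent, y axis) taken by 4 groups of features and by all others, for the 3 eAT and 3 vAT libraries (x axis). The 2 most abundant features of vAT took between 57.8% and 59.23% of the reads in vAT, and the features over 10 log2 units lower in eAT took between 8.53% and 10.4% of the reads there and too little to be seen in eAT.

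The RNA of eAT also differed after a day at 18 °C. Sizes here are on the variance-stabilised scale, which compresses differences between low values, so they cannot be set against those between eAT and vAT. Of 10059 genes tested, 1358 passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), 595 higher and 763 lower in the cold. The median log2 change was 0.66 among the calls that were higher and −0.71 among those that were lower, and 77 genes were higher and 131 lower by more than 1. The first principal component, which carried 52.4% of the variance, separated the 3 cold from the 3 control libraries.

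The fall of largest size among the calls was −3.10, in a gene outside the rule for named genes. Among genes that met the rule in all but a symbol, the largest rises in the cold were those of ENSDARG00000114451, from 8.04 ± 0.192 in control eAT to 10.89 ± 0.932 in cold eAT (variance-stabilised values, SD, n = 3 each, log2 change 2.85, SE 0.347, limma adjusted p = 0.000769), and of ENSDARG00000098315, from 8.20 ± 0.121 to 10.90 ± 0.524 (SD, n = 3 each, log2 change 2.698, SE 0.222, limma adjusted p = 7.77e-05). The largest falls were those of ENSDARG00000099002, from 10.65 ± 0.154 to 8.45 ± 0.0401 (SD, n = 3 each, log2 change −2.20, SE 0.137, limma adjusted p = 1.45e-05), and of ENSDARG00000099351, from 10.79 ± 1.03 to 8.62 ± 0.307 (SD, n = 3 each, log2 change −2.17, SE 0.386, limma adjusted p = 0.0049), whose call ended in the robust form of the test. The count of calls was 686 without control library ctr3, 803 without cold library cld1 and 897 without cold library cld3. It was 484 of 1373 genes under the stricter filter, which tests far fewer genes.

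The genes at the extremes of the depot comparison were looked up in the cold table, which was normalized separately and is on another scale. Of the 44 genes more than 10 log2 units lower in eAT than in vAT, 24 were listed in the cold table and the others have no value there. Of those listed, 1 passed its filter, and their library medians lay between 7.47 and 7.66, close to the lowest value of 7.33. All 25 genes that were more than 10 log2 units higher in eAT were listed and 24 passed the filter, with library medians between 13.5 and 14.1.

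In mouse eAT, lists of genes of mitochondrial energy metabolism and of heart muscle were higher in the aged libraries, and lists of the extracellular matrix and of fibroblasts were lower, at camera's preset correlation. With an estimated correlation 0 of the 26 lists tested passed, and most members of these lists did not pass the threshold singly. The median heart muscle marker lay at a percentile of at least 99.5 in each library, the median adipocyte gene between 69.3 and 73.6. The changes may thus not be those of fat cells alone. Of 12345 genes tested, 343 passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), 185 higher and 158 lower in aged mice, and most changes were small, with a median absolute change of 0.63 among the calls. The largest rises were those of Scn4b, a regulatory subunit of voltage-gated sodium channels, from 8.50 ± 0.13 to 10.98 ± 0.22 (variance-stabilised values, SD, n = 3 each, log2 change 2.48, SE 0.136, limma adjusted p = 1.31e-05), and of Cpxm2, a member of the carboxypeptidase family (log2 change 2.07, SE 0.132, limma adjusted p = 3.28e-05). Bdh1, the mitochondrial enzyme that interconverts the ketone bodies, rose by 1.83 (SE 0.171, limma adjusted p = 0.00092), the complement component C4b by 1.33 (limma adjusted p = 0.0038) and Scn4a, a sodium channel best known from skeletal muscle, by 1.22 (limma adjusted p = 0.0122). C4b shares most of its sequence with C4a, so the split of reads between both is uncertain. The largest falls were those of Grip2 (log2 change −1.57, limma adjusted p = 0.0327), of Eln, which encodes elastin (−1.38, limma adjusted p = 0.0199), of the inducible heat shock gene Hspa1b (−1.30, limma adjusted p = 0.0429), of Col1a1, a chain of type I collagen (−1.18, limma adjusted p = 0.0162), and of the imprinted gene Peg3 (−1.15, SE 0.137, limma adjusted p = 0.00303). Hspa1b shares nearly all of its coding sequence with Hspa1a, which stood at −1.19 (limma adjusted p = 0.0601, named after its value was seen), so both are uncertain.

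The mouse count depended on single libraries: 22 genes passed without o1, 20 without o2, 60 without o3, 137 without y1, 76 without y3 and 321 without y2. Of the 19 named mouse genes past the threshold, Scn4b, Cpxm2, Bdh1, C4b and Peg3 (5) kept their calls whichever library was left out, with log2 changes no smaller than 2.35, 1.99, 1.62, 1.19 and −1.04. Without o1 or without o2 the calls of Scn4a, Eln and Col1a1 ended, at changes no smaller than 1.07, −1.07 and −0.98. The call of Hspa1b ended without o1, o2, o3, y1 or y2, and that of Grip2 without any one library but o3. Grip2 had its lowest value in o3 (11.6) and stood at −1.09 without it.

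Oxidative phosphorylation, the respiratory chain and ATP synthase, was higher in aged eAT as a list. Of its 66 measured members 6 rose, none fell and 60 did not pass, and 35 rose when adjusted over the list alone. The median log2 change was 0.35 (camera adjusted p = 1.55e-18, and adjusted p = 0.285 with an estimated correlation). Sdhd, a subunit of succinate dehydrogenase, rose by 0.65 (SE 0.111, limma adjusted p = 0.0213) and Ndufa10, a subunit of complex I, by 0.61 (SE 0.134, limma adjusted p = 0.0408). Of 26 fatty acid oxidation genes 6 rose and none fell, 19 rose when adjusted over the list alone, and the median change was 0.46 (camera adjusted p = 2.48e-13, and adjusted p = 0.285 with an estimated correlation). Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, rose by 0.65 and Decr1, an enzyme for unsaturated fatty acids, by 0.63 (limma adjusted p = 0.0287 and 0.0213). Of 21 genes of the tricarboxylic acid cycle 3 rose, 16 when adjusted over the list alone, with a median change of 0.37 (camera adjusted p = 7.22e-12, and adjusted p = 0.285 with an estimated correlation). Sdhd was among them, as was Idh2, the mitochondrial isocitrate dehydrogenase, which rose by 0.62 (limma adjusted p = 0.0479). The cycle shares its 4 succinate dehydrogenase subunits with the respiratory chain list. Creatine and calcium cycling genes had a median change of 0.26 (camera adjusted p = 0.00923, and adjusted p = 0.429 with an estimated correlation). Of 14 members 2 passed the threshold, and 5 rose and 1 fell when adjusted over the list alone. They were Slc6a8, the creatine transporter, at 0.50 and Ckmt2, a mitochondrial creatine kinase, at 0.59, both named after their values were seen. The call of Slc6a8 ended without any one library but y2 and that of Ckmt2 without any one library, at changes no smaller than 0.47 and 0.49.

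The list of heart muscle markers was also higher at the preset correlation alone. The 21 cardiomyocyte markers had a median change of 0.40, close to those of the oxidative lists, and 20 of the 21 were higher in aged eAT (camera adjusted p = 1.58e-08, and adjusted p = 0.285 with an estimated correlation). The list shares 3 genes with the creatine and calcium list and 1 with the smooth muscle list. Only Tcap, a protein of the sarcomere's Z disc, passed the threshold, at 0.74 (SE 0.169, limma adjusted p = 0.0449), and 7 markers rose when adjusted over the list alone. Without any one of o1, o2 and o3 the calls of Sdhd, Ndufa10, Etfdh, Decr1, Idh2 and Tcap ended, without y3 all of these but that of Decr1, and without y1 those of Ndufa10, Etfdh, Idh2 and Tcap. Their changes were then no smaller than 0.59, 0.50, 0.58, 0.61, 0.51 and 0.58, and without o2 the creatine and calcium list lost its call at a median of 0.18, while without y3 that median was 0.15. The call of that list also ended with a mean of at least 3 above the lowest value, at a median of 0.21 (camera adjusted p = 0.07).

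Heart muscle markers stood above adipocyte genes in every mouse library by the medians of both lists. The median cardiomyocyte marker lay at 14.5 ± 0.0961 in aged and 14.03 ± 0.106 in young eAT (variance-stabilised values, SD, n = 3 each), at a percentile of at least 99.5 among the genes tested. The median gene of adipocyte identity and lipid storage lay at 9.66 ± 0.0915 in aged and 9.62 ± 0.0456 in young eAT (SD, n = 3 each), at a percentile between 69.3 and 73.6. Ttn, which encodes titin, lay between 18.3 and 18.8 and Myh6, the heart's alpha myosin heavy chain, between 17.5 and 18.4, both named after their values were seen. Among adipocyte genes, Fabp4, a fatty acid carrier, lay between 11.2 and 12.2, while Plin1, which coats lipid droplets, and Adipoq, the hormone adiponectin, lay between 7.62 and 8.28 and between 7.13 and 7.70. Neither passed the threshold (log2 changes −0.03 and −0.20, limma adjusted p = 0.951 and 0.487), nor did Fabp4 (−0.22, limma adjusted p = 0.543). With 1 library left out, Adipoq lay between −0.10 (without o1) and −0.33 (without y2), and Fabp4 between −0.03 (without o2) and −0.36 (without o3). The sign for Plin1 turned without o1 (0.18) and without y3 (0.0019). Of the 30 measured genes of adipocyte identity and lipid storage only Slc2a4, the insulin-responsive glucose transporter, which heart muscle also uses, passed the threshold (0.73, limma adjusted p = 0.0197, named after its value was seen). That call ended without o1, o2, o3 or y3, at changes no smaller than 0.66. The list's median change was 0.09 (camera adjusted p = 0.278), and 5 rose and 1 fell when adjusted over the list alone.

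**Figure D2:**
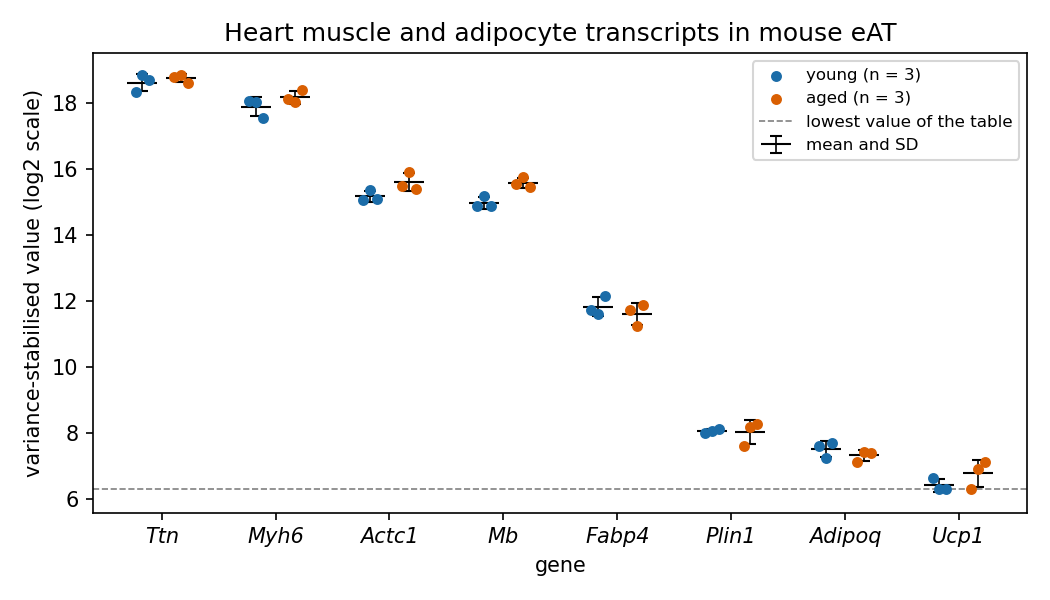
Variance-stabilised values (log2 scale, y axis) of 4 heart muscle genes and 4 adipocyte genes (x axis) in the young and aged mouse eAT libraries. Points are libraries, bars the mean and SD of 3, and the dashed line the lowest value of the table. Ttn and Myh6 lay above 17 in every library and Adipoq below 8.

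The list of genes that mark beige and brown fat was higher in aged eAT at camera's preset correlation alone, by a small median. Which cells these transcripts came from was not tested. None of the 20 measured members of the thermogenic list passed the threshold in limma over all genes. At an unadjusted p under 0.05, 8 were higher and 1 was lower, and 7 rose and 1 fell when adjusted over the list alone. The list shares Cox8b and Cox7a1 (named after their values were seen), both among those 8, with oxidative phosphorylation and Cpt1b with fatty acid oxidation. The list's median change was 0.12 (camera adjusted p = 0.0172, and adjusted p = 0.482 with an estimated correlation). Cidea, a lipid droplet protein of brown adipocytes, stood at 0.34 (limma adjusted p = 0.135), Ppargc1a, a coactivator of mitochondrial genes, at −0.30 (limma adjusted p = 0.405), Dio2, which activates thyroid hormone, at −0.15 (limma adjusted p = 0.692) and Prdm16, a determinant of brown fat fate, at −0.08 (limma adjusted p = 0.824). With 1 library left out, Ppargc1a lay between −0.18 (without o3) and −0.53 (without y1). The sign turned for Dio2 without o2 (0.0034) or without y1 (0.03) and for Prdm16 without o3 (0.05). The list's call ended without o2 (median 0.10), without y3 (0.09) and with no filter on genes (0.03), and its median was 0.23 without o3 and 0.22 without y2. Ucp1, the uncoupling protein of brown and beige fat, averaged 6.78 ± 0.418 in aged and 6.42 ± 0.194 in young eAT (SD, n = 3 each), near the lowest value of 6.31 and below the filter, as did Lep, which encodes leptin (6.64 and 6.55), and Cdkn2a, a marker of senescence (6.96 and 6.46). The values of Ucp1 and Lep overlapped between groups. Those of Cdkn2a did not: its lowest aged library stood at 6.921 and its highest young library at 6.564. Below the filter this difference was not tested, and the senescence list was measured without Cdkn2a.

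The list of extracellular matrix genes was lower in aged eAT at camera's preset correlation alone. Of 35 measured members 13 fell, 1 rose and 21 did not pass, 21 fell and 1 rose when adjusted over the list alone, and the median change was −0.43 (camera adjusted p = 4.03e-12, and adjusted p = 0.285 with an estimated correlation). Besides Eln and Col1a1, the fibrillar collagen Col3a1 fell by 1.13 and Sparc, a collagen-binding protein, fell by 1.02 (limma adjusted p = 0.0213 and 0.00276, both named after their values were seen). The member that rose was Mmp3, a matrix-degrading protease (0.61, limma adjusted p = 0.0445, also named after its value was seen). Of 23 fibroblast and adipose progenitor markers 4 fell and none rose (13 fell and 1 rose when adjusted over the list alone), with a median change of −0.40 (camera adjusted p = 1.34e-06, and adjusted p = 0.285 with an estimated correlation). Among them Mfap5, a microfibril protein, fell by 0.83 (SE 0.163, limma adjusted p = 0.0287) and Fmod, fibromodulin, fell by 0.73 (SE 0.124, limma adjusted p = 0.0213). The call of Mfap5 ended without o1, o2, y2 or y3 (no smaller than −0.75), those of Fmod and Col3a1 without o1, o2 or o3 (no smaller than −0.63 and −0.90), and that of Mmp3 without any one library (no smaller than 0.53).

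Lists of markers of other cells of the heart's surface and vessels were lower at camera's preset correlation, with few members past the threshold, and did not pass with an estimated one. Of 13 epicardium and mesothelium markers 1 fell, Aldh1a2, the retinoic acid synthesis enzyme of the epicardium (−0.67, SE 0.129, limma adjusted p = 0.028), and the median change was −0.30 (4 fell when adjusted over the list alone, camera adjusted p = 0.000669, and adjusted p = 0.429 with an estimated correlation). None of 17 smooth muscle and pericyte markers passed the threshold in limma. At an unadjusted p under 0.05, 8 were lower and 1 was higher, and 7 fell and 1 rose when adjusted over the list alone. Their median was −0.35 (camera adjusted p = 0.00678, and adjusted p = 0.465 with an estimated correlation). The 2 with the smallest p were Mylk, myosin light chain kinase (−0.49, limma adjusted p = 0.0613), and Lmod1, leiomodin (−0.67, limma adjusted p = 0.0689). Of 22 endothelial and lymphatic markers 1 fell, the receptor Tek (−0.60, limma adjusted p = 0.0318, named after its value was seen), with a median of −0.16 (1 fell when adjusted over the list alone, camera adjusted p = 0.0172, and adjusted p = 0.478 with an estimated correlation). Aldh1a2 and Tek lost their calls without o1, o2, o3, y1 or y3 (no smaller than −0.58 and −0.52), the endothelial list lost its call without o2 (−0.10) and without y3 (−0.12), and the epicardial median was −0.18 without y3. With a mean of at least 3 above the lowest value, the smooth muscle list lost its call at a median of −0.22 (camera adjusted p = 0.118), as did the endothelial list at −0.16 (adjusted p = 0.0735).

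**Figure D3:**
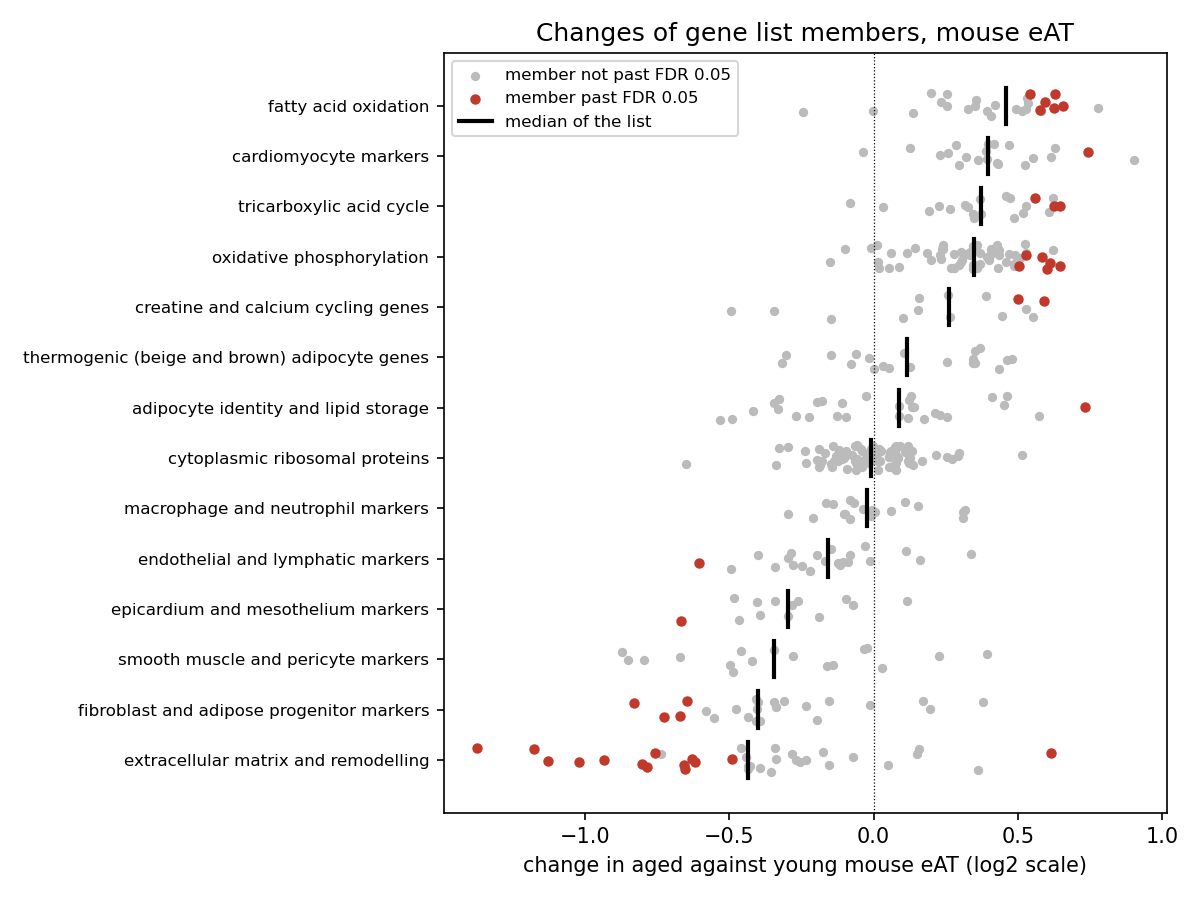
Change of each measured list member in aged against young mouse eAT (log2 scale, x axis; 3 libraries per group) for the 11 lists past the threshold and for 3 others (y axis). Points are genes, red where limma's adjusted p was under 0.05, and black bars are list medians, which ran from −0.43 for the extracellular matrix to 0.46 for fatty acid oxidation, with cytoplasmic ribosomal proteins at −0.0080.

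The other 15 lists tested did not pass in camera. In the list of heat shock and cold-inducible RNA-binding proteins 5 of 24 members fell and 1 rose (6 fell and 4 rose when adjusted over the list alone, median −0.12, camera adjusted p = 0.32). Hsp90aa1, Dnaja1, Hsph1 and Serpinh1, all protein chaperones, fell by 0.70, 0.67, 0.58 and 0.57 beside Hspa1b, while Hspb8, a small heat shock protein abundant in muscle, rose by 0.75 (limma adjusted p = 0.0253, 0.03, 0.0262, 0.0293 and 0.0263, all named after their values were seen). Without any one of o1, o2, o3 and y3 the calls of these 5 genes ended (no smaller than −0.58, −0.58, −0.54, −0.52 and 0.63), and without y1 those of Dnaja1, Hsph1 and Serpinh1. Median changes were −0.14 for nerve and Schwann cell markers and −0.10 for the endoplasmic reticulum stress response (camera adjusted p = 0.0841 for both), −0.10 for interferon-stimulated genes (adjusted p = 0.253), 0.12 for skeletal muscle markers (adjusted p = 0.567), 0.0053 for heart-field and epicardial transcription factors, −0.05 for fatty acid and sterol synthesis, −0.0048 for circadian clock genes and 0.03 for inflammatory cytokines and acute phase (adjusted p = 0.812 for these 4). They were −0.01 for senescence and −0.02 for cell cycle genes (adjusted p = 0.819 for both), −0.02 for macrophage and neutrophil markers (adjusted p = 0.849), −0.0080 for cytoplasmic ribosomal proteins (adjusted p = 0.885) and −0.04 for B and plasma cell markers (adjusted p = 0.387). For the clock, cell cycle, macrophage, ribosomal protein and B cell lists camera's direction was upward, against the sign of the median, and for the clock, cell cycle and B cell lists the mean too was positive. Single members rose in 4 of these lists, named after their values were seen: Bhlhe41 of the clock (0.63), Cenpf of the cell cycle (0.70), Mmp3 of senescence and the immunoglobulin gene Ighg2c (1.71, limma adjusted p = 5.94e-05). The calls of Bhlhe41 and Cenpf ended without any one library but y3, at changes no smaller than 0.52 and 0.59. Ighg2c kept its call without o1, y1, y2 or y3 and fell below the filter without o2 or o3. Its reads are uncertain, since its family members share sequence. Lists with fewer than 5 measured members were not tested: erythrocyte markers (2 measured, of which Alas2, named after its value was seen, rose by 0.85, a call that ended without o1, o2, o3 or y3, no smaller than 0.68), Hox genes (2, median −0.11), liver (2, −0.07), thymus (2, 0.14), lung and airway (1, 0.22), T and natural killer cells (1, 0.31) and ovary and oocyte markers (0).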

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

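The alternatives for the gene and list tests were chosen before the data were examined. Between eAT and vAT the count of 2226 genes lay between 1855 (a mean of at least 50 normalized counts) and 3105 (DESeq2 on whole reads, which made 16.8% false calls on simulated reads) under the settings that kept all libraries. edgeR on whole reads called 2436, of which 2130 were among the 2226. Leaving out 1 library gave between 1315 and 2346. Quantile normalization moved the median change of all tested genes from 0.22 to 0.06 and edgeR moved it to 0.04, so small changes are relative to that choice. With the replicate number as a block 2520 genes passed. Whether equal numbers pair the libraries was not settled. The deviations of same-numbered libraries from their group means correlated at 0.032, 0.175 and 0.135, and those of other pairs between −0.169 and 0.0466. For vAT replicate 1 the best match was eAT replicate 3 (0.0466), while the other vAT libraries correlated best with their own number. Between cold and control eAT the count of 1358 fell to 484 with a mean of at least 3 above the lowest value, where 1373 genes were tested, and lay between 686 and 1015 with 1 library left out. In mouse eAT the count of 343 lay between 20 and 321 with 1 library left out, and quantile normalization gave 63.9% of calls as higher against 53.9%. The count of lists past the threshold, 11, was 0 with an estimated correlation (the same lists at unadjusted p between 0.0418 and 0.26) and 7 with a mean of at least 3 above the lowest value, where 21 lists were tested. There the smooth muscle (−0.22, adjusted p = 0.118), creatine and calcium (0.21, adjusted p = 0.07) and endothelial lists (−0.16, adjusted p = 0.0735) lost their calls, and the epicardium list had too few members. With 1 library left out between 8 and 12 lists passed, of which between 8 and 11 were among the 11. Among named genes, 55 of 216 values with 1 library left out and 8 of 222 values under other settings kept their direction but lost the threshold, and 1 of each gained it. For lists the losses were 5 of 66 and 15 of 76. Signs turned with 1 library left out for Plin1 (−0.15 to 0.18), Dio2 (−0.28 to 0.034) and Prdm16 (−0.23 to 0.047), none of them past the threshold in those fits. Genes below a stricter filter have no value there. Under other settings with all libraries, calls ended for ENSDARG00000099351, Grip2 and Hspa1b with the robust form, for Ndufa10, Idh2 and Tcap with no filter, and for Idh2 and Tcap with quantile normalization. Where no fewer genes, lists or libraries entered, the cause was not tested. The zebrafish list tests and fixed zebrafish names were not run for lack of names. Depth limits the vAT libraries, where 1 read is worth between 1.28 and 2.65 normalized counts against 0.268 to 0.697 in eAT.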

Other observations

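Further mouse genes, all named after their values were seen, changed in aged eAT. Myot and Ankrd1, proteins of the sarcomere, rose by 1.37 and 1.02 and Hspb7, a small heat shock protein of heart muscle, by 1.12 (limma adjusted p = 0.001, 0.003 and 0.00687), and these calls held whichever library was left out. The complement genes C3 and Cfb rose by 0.88 and 0.80 (limma adjusted p = 0.0197 and 0.0164) beside C4b, and both calls ended without o1, o2 or o3 (no smaller than 0.79 and 0.72). Igf2, an imprinted growth factor like Peg3 in its imprinting, fell by 0.98 (SE 0.106, limma adjusted p = 0.00173), from 11.16 ± 0.0322 to 10.19 ± 0.0306 (SD, n = 3 each), and its call held whichever library was left out. Igf1 fell by 0.72 (limma adjusted p = 0.0369), a call that ended without o1, o2, o3, y1 or y3 (no smaller than −0.60). Lars2 is named for its spread between libraries, not as a change with age. It stood at 14.8 in library o3 and between 19.4 and 21.4 in the other mouse libraries. Grip2, the largest of the named falls, was also lowest in o3 (11.6). Both genes stood lower in o1 and o2 than in every young library. Whether their spreads share a source was not tested.

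The tests of the heart muscle share, of the other cell types, of the size factors, of one source in vAT and, in its final form, of the cold response were chosen after the result was seen. At camera's preset correlation the oxidative lists were higher and the matrix and fibroblast lists lower in aged mouse eAT, and with an estimated correlation none of these lists passed (adjusted p = 0.285). A trend with gene length or GC content was argued against: with each library's trend removed, 4 of the 4 lists with the smallest p stayed past the threshold at the preset correlation, with medians of 0.32 (oxidative phosphorylation), 0.43 (fatty acid oxidation), −0.36 (extracellular matrix) and 0.37 (tricarboxylic acid cycle). A lower share of all cells other than heart muscle could not be decided on as a cause of the lower matrix and fibroblast lists. Fibroblast markers lay below macrophage markers by −0.378 (two-sided permutation test over 23 and 20 markers, p = 0.00024, genes are not independent replicates). The lists were compared after their medians were seen, and the test shuffled genes rather than libraries. Its p thus restates a gap already seen and decides nothing about an equal fall. By library the fibroblast list averaged 9.941 ± 0.0615 in aged and 10.28 ± 0.0754 in young eAT (SD, n = 3 each). The macrophage list averaged 9.108 ± 0.074 and 9.11 ± 0.11 (SD, n = 3 each), so no fall of that size was seen in it. A separate change of the macrophage markers was not excluded, but their counts do not show one. At an unadjusted limma p under 0.05, 3 of the 20 were higher and 1 was lower. Of all 12345 genes tested 2481 lay under 0.05, which is about the same share. The smooth muscle (−0.35), epicardium (−0.30), endothelial (−0.16) and nerve markers (−0.14) were lower too, as a lower share would make them. A lower share therefore stays open, as a part of the cause or as the whole. No sort is described in the labels beyond the collection of adipocytes. A higher share of heart muscle RNA in the aged libraries cannot be told apart from a change within the cells for the oxidative lists, because the mitochondrially encoded transcripts, which heart muscle holds in plenty, changed by a mean of −0.113 with a standard error over libraries of 0.321. Their median change was −0.0392, and the 13 transcripts ranged from −1.08 to 0.116, so none reached the 0.40 of the cardiomyocyte markers. Their mean lies within 2 standard errors of 0.40, so the spread between libraries keeps the explanation open. A smaller share of fibroblasts, and age itself, stay open as untested explanations.

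The 44 zebrafish genes more than 10 log2 units lower in eAT than in vAT were set by that cut, and 196 called genes were lower by more than 5. Under TMM scaling, quantile normalization and edgeR on whole reads 44 of the 44 stayed past the threshold and lower in eAT. Their falls were no smaller than −10.46. That outcome cannot decide on the size factors as a cause, since the genes were chosen for falls over 10. These settings moved the median change of all tested genes only from 0.22 to 0.175, 0.0643 and 0.0397, so the calls could hardly end. In shares of reads, which use no size factor, the 44 took 9.28% ± 0.985 in vAT and 0.000503% ± 0.000151 in eAT (SD, n = 3 each). These shares argue against the size factors as the cause of the fall of these 44 genes as a set. RNA of one other source in the vAT libraries may contribute, since one source keeps its transcripts in one ratio: the SD of the genes' log2 ratios between vAT libraries was at most 0.364, in each pair under the 5th percentile of 1000 sets matched on abundance (0.451, 0.477 and 0.447). Each set was drawn from the 200 genes nearest in level in vAT. Too few genes reach the level of the most abundant of the 44, so the sets lie lower there. The 44 were also cut from these same data, so the match is loose. Genes under one shared control within the adipose cells of vAT would also keep one ratio, so a difference between the depots themselves stays open. Without gene names no source can be named.

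Whether cold moves eAT toward the profile of vAT stayed open. Across 8996 genes tested in both tables the changes correlated at r = −0.0425 (across genes, which are not independent replicates). Genes higher in eAT than in vAT had a median change in the cold of −0.0631 (camera p = 0.153, and p = 0.642 with an estimated correlation), and genes lower in eAT had one of −0.0536 (camera p = 0.0477, and p = 0.208 with an estimated correlation). The criterion first set for this test asked for the preset correlation alone, and by it the value of −0.0536 spoke against such a move. After that result was seen an estimated correlation was required as well, because the call ends with it. Of the 1005 genes higher in eAT, 144 were lower in the cold where independent lists would share 78.0, and 93 were higher in the cold where they would share 60.7 (Fisher's exact test, adjusted p = 1.59e-13 and 3.32e-05 over 4 overlaps). Fisher's test counts genes as independent, which they are not, so its p-values are likely too small. Both overlaps lay above independence (odds ratios 2.24 and 1.71), so they give the response no direction. Of the 436 genes lower in eAT, 47 were lower in the cold (33.8 by independence, adjusted p = 0.0284) and 23 were higher (26.3, adjusted p = 0.606). These 436 are the part of the 1065 genes called lower in eAT that passed the filter of the cold comparison. Of the 1161 called higher, 1005 passed it. Of the 44 genes more than 10 log2 units lower, 1 passed it. A rise of the missing genes in the cold could not be seen here or in the camera test. The tables share no library.

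With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, reached the real count. The other splits called at most 0 genes where the real one called 2226 (eAT against vAT), at most 0 where it called 1358 (cold against control) and at most 3 where it called 343 (aged against young).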
